A study of Mus musculus with 2 samples.

How the data were processed

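Per the labels, RNA was measured in 2 mouse liver libraries, 1 from a sham-treated control and 1 from a liver kept cold after removal. Per the labels' protocols, livers were flushed with UW solution, a preservation fluid used for donor organs, and kept in it at 4 °C for 12 or 24 h. The labels do not say which of these times applies to the cold-storage library. Per the labels' protocols, total RNA was extracted with TRIzol, and cDNA libraries were built with a commercial kit and amplified by PCR. No source names a depletion of ribosomal RNA, a selection of poly(A) RNA or a strand-keeping step.

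The deposited table holds RPKM, with 1 column per library. By definition RPKM is a read count divided by the length of the gene model and by the mapped reads of the library. The column names carry the codes that the labels give for the 2 libraries, and 0 further columns of values were left out. The aligner, the counter and the annotation are not given in the sources used here. The submitters' processing notes name the genome build mm9. Each row has an identifier (XLOC with a number, called its row number below) and a locus, and no gene symbol. These numbers are not consecutive. The loci run past the ends of the mouse chromosomes, so they were not treated as mm9 or GRCm38 positions. They are printed as deposited, in a build that is not given in the sources used here. No genome other than mouse was used here, so neither the species of the gene models nor that of the RNA was established. The mouse origin of the values therefore rests on the labels alone.

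No reference for the loci was used here, so no row was given a gene name, an exon, an intron or a UTR. The 23 gene lists fixed before the data were examined held 381 distinct symbols, of which 0 matched a row name. None of these lists, which covered long non-coding RNAs, stress and metabolic genes and cell type markers, could be read. All rows fell into 1 name class. For the same reason at most 2 row numbers are named per direction. The others that the size rule selects are given as counts and ranges, or by position.

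With 1 library per group there is no replicate error, so no test of a difference between the groups, standard error or p-value was computed. The checks of explanations in the closing section compare rows, which are not independent replicates, and the 1 interval given there comes from resampling rows. Differences between the libraries cannot be set against the spread between animals. Each row was compared as the log2 ratio of cold storage over sham on the log2(RPKM + 0.1) scale, which understates the change of low rows. Rows with a mean RPKM of at least 0.5 and a value above 0 in both libraries were compared. A row was called higher or lower at a ratio of at least 2-fold. Rows listed at 0 in 1 library were counted apart, without a fold, because an exact 0 in such a table can also be a failed estimate. The rule for named rows, fixed before the data were examined, took the 12 highest and 12 lowest ratios. It also took the 5 highest rows listed at 0 in the other library, each way, and the 10 most abundant rows. Its last part, 2 abundant and 2 strongly differing members of each gene list, selected no row.

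The table holds no read counts, so the total depth is unknown and no counting interval is given. The low end of the values was compared in its place, although some values were too small to be whole reads. The 5% quantile of values above 0 was 0.0192 RPKM in the sham library and 0.00125 RPKM in the cold-storage library. RPKM is a share of mapped reads, so the 2 columns are comparable only as far as their divisors are. Log2 ratios are therefore also given relative to their median over the compared rows, which is one of the scalings fixed before the data were examined.

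The alternatives were other pseudocounts (0.01 and 1), other floors on the mean RPKM (none, 0.1, 1 and 5), 3 other scalings and thresholds of 1.5-fold and 4-fold. Leaving out rows that share a locus, rows under 1 kb and rows past the last mouse gene was chosen after seeing the data. The comparison was tested on simulated data over 3592 rows. Of 200 rows drawn with over 200 reads and changed 4-fold, 100% were called, and 0 of 48 unchanged rows of like depth were called. This simulation holds counting error only, with no variation between animals or libraries, and at this depth it checks the arithmetic of the comparison and not its power. Shallower rows were not part of it. The positions were set against mouse genes of GRCm38 from RefSeq and GENCODE M21. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.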

Results

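According to its labels, the data set compares RNA in the liver of male C57BL/6 mice, a common inbred strain, after sham treatment and after cold storage. Some positions in the table lie beyond any mouse chromosome of that name, so the mouse origin of every value below rests on the labels alone. The series was set up to profile long non-coding RNAs in livers injured by cold. It holds 2 libraries, 1 per group, so every difference below is between 2 libraries and has no replicate check. The table lists 3592 rows, each a gene model with a locus, on chromosomes 1 to 19, X and Y. Spans of the loci ran from 141 bp to 2113843 bp, with a median of 61988 bp. RPKM summed to 138892 in the sham library and 87310 in the cold-storage library over these rows. A total of 2544 rows were above 0 in the sham library and 2688 in the cold-storage library, and 1640 rows were above 0 in both. No row was at 0 in both.

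Part of the loci lay past the ends of the mouse chromosomes that the labels imply. On chromosome 2 the last locus ended at 242.3 Mb, whereas the last annotated mouse gene in GRCm38 ends at 182.0 Mb. Chromosome 1 loci reached 247.5 Mb, against 195.3 Mb for mouse genes. In all, 406 rows (11.3%) on 12 chromosomes started past the last GRCm38 mouse gene of the chromosome with the same name. No mm9 annotation was used, so rows just past these gene ends may lie within an mm9 chromosome. On chromosomes 13, 14 and 15 the first loci started at 20.2, 20.9 and 22.9 Mb. The rows far past these gene ends carried signal in both libraries. Of the 319 rows that started over 5 Mb past the last mouse gene, 225 were above 0 in the sham library, 240 in the cold-storage library and 146 in both. Their highest values were 395.5 RPKM in the sham library and 27.7 RPKM in the cold-storage library. These positions therefore could not be matched to mouse genes, and the values below are given by locus.

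**Figure D1:**
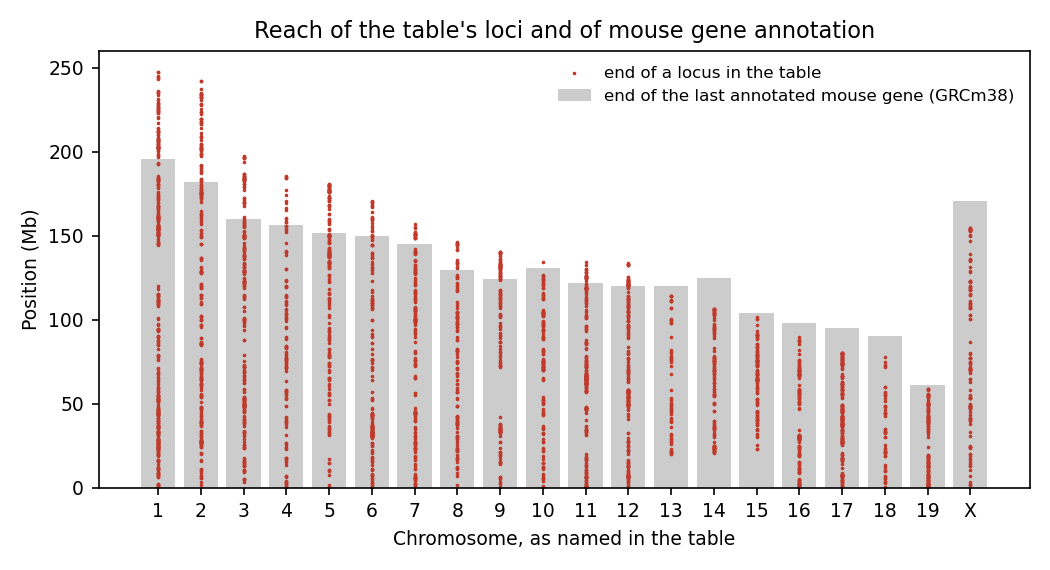
Position in Mb (vertical axis) of the end of each locus in the table (red points) on chromosomes 1 to 19 and X, with the end of the last annotated mouse gene in GRCm38 as grey bars. Loci on chromosome 2 reach 242.3 Mb, past the last mouse gene at 182.0 Mb, and 12 chromosomes hold rows that start past their last mouse gene.

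RPKM was lower in the cold-storage library at nearly every compared locus. Of 962 rows with a mean RPKM of at least 0.5 and a value above 0 in both libraries, 885 (92.0%) were at least 2-fold lower in cold storage, 12 (1.25%) were at least 2-fold higher and 65 (6.76%) lay within 2-fold. The median log2 ratio of cold storage over sham was -3.50, which is 11.3-fold lower on the RPKM + 0.1 scale, with quartiles of -4.43 and -2.56. With no floor, 1224 of 1640 rows were at least 2-fold lower and 22 at least 2-fold higher. The size of the shift depended on the settings: the median was -2.04 with a pseudocount of 1 and -2.37 with no floor. It was -0.67, with 225 higher and 468 lower rows, when both libraries had the same RPKM total without the 10 most abundant rows. Relative to the median ratio, 234 rows were at least 2-fold higher, 220 were at least 2-fold lower and 508 lay within 2-fold. Of the 885 lower rows, 157 lay at least 2-fold above that median. Across rows, which are not independent replicates, log2 values of the 2 libraries had a Pearson r of 0.76 and a Spearman rho of 0.67.

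**Figure D2:**
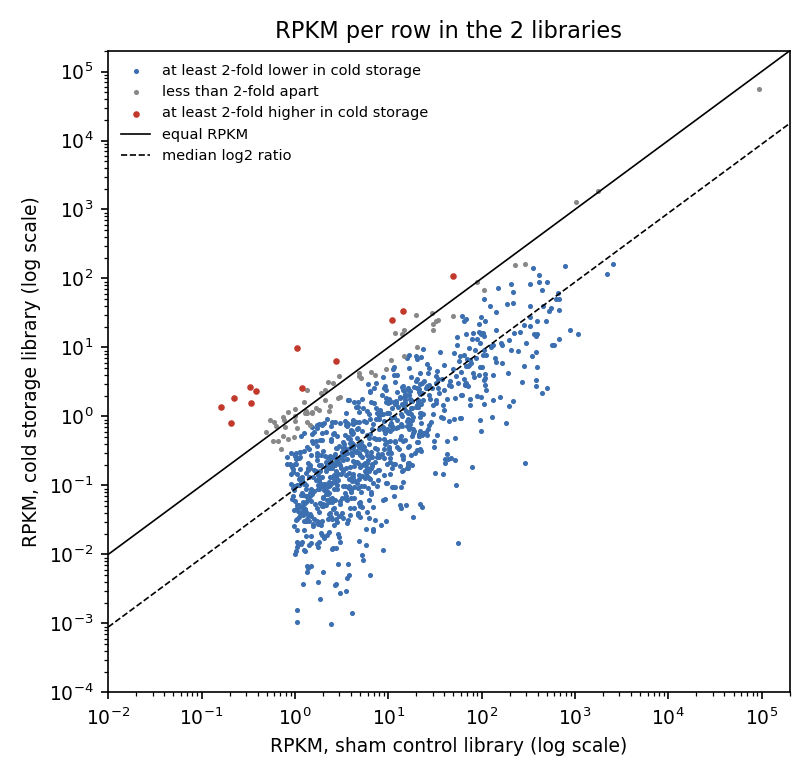
RPKM of each of the 962 compared rows in the sham library (horizontal axis, log scale) and the cold-storage library (vertical axis, log scale), with 1 point per row and 1 library per group. Most points lie below the line of equal RPKM, around the dashed line of the median log2 ratio of -3.50; relative to that line 234 rows are at least 2-fold higher and 220 at least 2-fold lower.

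The quantiles of the values were shifted between the libraries, although the most abundant rows were not shifted alike. Among rows above 0, the median was 0.651 RPKM in the sham library and 0.0462 RPKM in the cold-storage library. The 95% quantiles were 65.1 and 4.87 RPKM. Rows listed at 0 were about as frequent in each library, with 1048 in the sham library and 904 in the cold-storage library. With no pseudocount and no floor, the median log2 ratio over the 1640 rows above 0 in both was -3.81.

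**Figure D3:**
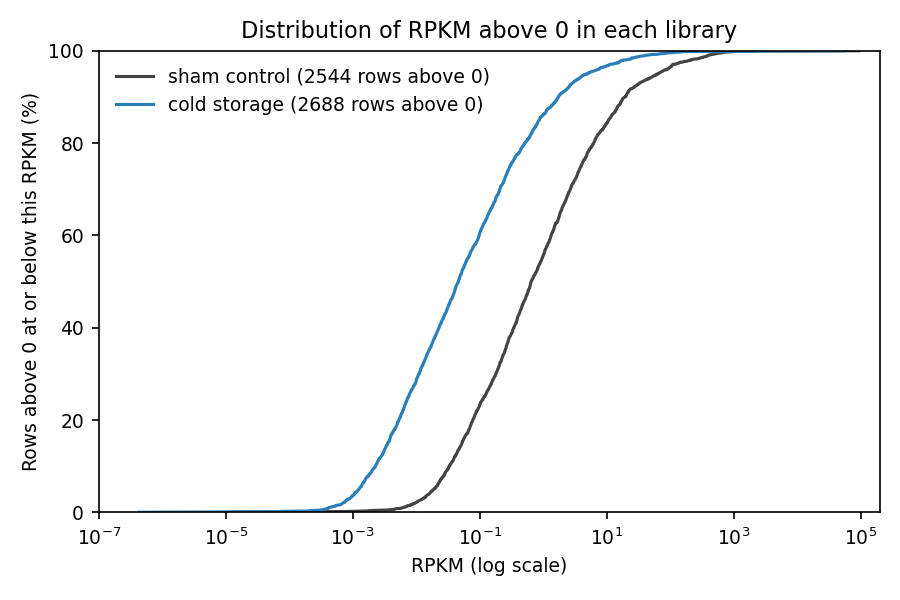
Percent of rows above 0 (vertical axis) at or below each RPKM (horizontal axis, log scale) in the sham library (2544 rows) and the cold-storage library (2688 rows). The cold-storage curve lies to the left of the sham curve, with medians of 0.0462 and 0.651 RPKM.

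The 12 loci that were higher in cold storage were spread over 8 chromosomes. Chromosome 17, with 77 of the 962 compared rows, held 4 of them, and 2 of the 12 share their locus with another row. Their log2 ratios ran from 1.05 to 3.11. Most were low in the sham library, with 8 of the 12 under 1.5 RPKM there. The highest ratio was at XLOC_020513 on chromosome 17, from 36921941 to 36956379, with 1.06 RPKM in the sham library and 9.96 RPKM in cold storage. That log2 ratio of 3.11 stood 6.61 above the median of all compared rows. The most abundant of the 12 loci, at 64979771 to 65011801 on chromosome 15, had 49.7 RPKM in the sham library and 109.1 RPKM in cold storage.

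The 12 loci with the lowest ratios lay on 10 chromosomes and had log2 ratios from -9.85 to -7.09. All 12 were well above the floor in the sham library, at 18.3 to 505.9 RPKM, and at 0.0148 to 2.61 RPKM in cold storage. The lowest was XLOC_014659 on chromosome 14, from 65381078 to 65569413, with 290.5 RPKM in the sham library and 0.214 RPKM in cold storage. Its log2 ratio was -9.85 as deposited and -6.36 relative to the median. Another row shares this locus, and how the authors' counting divided reads between the 2 gene models is not given in the sources used here. That row was listed at 0 in the sham library and had 0.00153 RPKM in cold storage. The most abundant locus in this set, at 155504277 to 155511918 on chromosome 4, had 505.9 RPKM in the sham library and 2.61 RPKM in cold storage.

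Some loci were listed at 0 in 1 library. Among the rows past the floor of 0.5, 40 were listed at 0 in the sham library and 207 in the cold-storage library. The floor is on the mean, so it passes rows seen only in the sham library, where values are higher, more easily. Over all rows the order was the opposite, with 1048 rows listed at 0 in the sham library and 904 in cold storage. XLOC_039512, a locus of 331 bp on chromosome 6 from 52860417 to 52860748, had 24218 RPKM in cold storage and was listed at 0 in the sham library. It was the only one of the 40 rows at that level, since the next highest had 23.04 RPKM. No other row overlapped it. In the opposite direction, XLOC_015646 on chromosome 15, from 63900816 to 64126141, had 46.5 RPKM in the sham library and was listed at 0 in cold storage. It shares its locus with a row at 0.192 RPKM in the sham library and 0.0129 RPKM in cold storage. The median sham value of the 207 rows listed at 0 in cold storage was 2.503 RPKM.

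The most abundant loci did not follow the general shift alike. A locus of 141 bp on chromosome 12, from 120729565 to 120729706, held 67.3% of the RPKM sum in the sham library and 63.5% in cold storage. RPKM divides by length, so these are not shares of reads. The locus held at most 1.32% of the reads in the sham divisor and 0.78% in the cold-storage divisor. Its values were 93419 and 55427 RPKM, a log2 ratio of -0.75 as deposited and 2.74 relative to the median. A neighbouring locus of the same length, from 120730899 to 120731040, had 1763 RPKM in the sham library and 1861 RPKM in cold storage. A locus on chromosome 3, from 15708742 to 15901278, had 1031 and 1295 RPKM. In contrast, a locus on chromosome 4 from 103717132 to 103790053 had 2556 RPKM in the sham library and 164.2 RPKM in cold storage. A locus on chromosome 11 from 10804832 to 10830657 had 2225 and 115.4 RPKM, and a locus on chromosome 19 from 42363987 to 42376994 had 1073 and 15.6 RPKM. Of the 10 most abundant rows, 6 were at least 2-fold lower in cold storage as deposited.

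The shift was present on every chromosome with at least 20 compared rows. Median log2 ratios ran from -3.83 on chromosomes 14 (51 rows), 8 (36 rows) and 5 (59 rows) to -2.71 on chromosome 19 (32 rows). By span, the 21 compared loci under 1 kb had a median of -2.26. The 97 loci of 1 to 10 kb had a median of -3.09, the 478 loci of 10 to 100 kb one of -3.63, and the 366 longer loci one of -3.46. The 103 compared rows past the last mouse gene had a median of -3.79, with 98 lower and 0 higher. The 859 other rows had a median of -3.45, with 787 lower and 12 higher. These medians describe 2 libraries, and the differences between them were not tested.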

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

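With 1 library per group no library could be left out and no test was run, so the alternatives show only how far the counts and the median move. The direction of the median log2 ratio was negative under every setting that gives one. It was -2.04 with a pseudocount of 1, -2.37 with no floor on low values, and -0.67 when both libraries were scaled to the same RPKM total without the 10 most abundant rows. That last scaling gave 225 higher and 468 lower rows, and centring on the median gave 234 and 220, against 12 and 885 as deposited. The same RPKM total over all rows gave 28 higher rows. The count of higher rows was 22 with no floor, 21 with a floor of 0.1, 4 with a floor of 5 (370 lower) and 5 at a threshold of 4-fold. Floors change the number of rows compared, from 397 with a floor of 5 to 1640 with none. For the other shifts the cause was not tested. The 3 settings chosen after seeing the data left out rows sharing a locus, rows under 1 kb or rows past the last mouse gene. They gave 10 to 12 higher rows and medians of -3.51, -3.51 and -3.45. The ratio of XLOC_020513 stayed between 2.41 and 6.61 and that of XLOC_014659 between -10.3 and -6.36. Alternatives for the gene lists gave no value because no list matched a row, and those for the name classes equal those for all rows. The depth is unknown, so rows of low RPKM cannot be separated from counting error.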

Other observations

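All tests in this part were chosen after the results were seen, except the match of locus spans to mouse gene spans.

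Of the 3592 rows, 406 (11.3%) started past the last annotated mouse gene of their chromosome. The values argue against 2 explanations, the first only for models that kept the annotated gene ends. Gene models of another mouse build would keep their spans if they had the annotated ends. Only 6.57% of the loci had the span of an annotated mouse gene on their chromosome, under either way of counting the first base. In 100 shuffles of the chromosomes the median was 7.29% and the highest value 7.99%. Loci merged from several gene models would lower this share, and 416 rows share their locus. No set of known mouse models was run for comparison. The bound of 5% set beforehand was too strict, because shuffling alone exceeds it. Reads aligned to a mouse genome could not reach loci past its ends, yet 146 of the 319 rows starting over 5 Mb past the last mouse gene were above 0 in both libraries, at up to 395.5 RPKM in sham. A candidate explanation that stays open is a genome with autosomes numbered above 19, such as human: in text order these fall between chromosomes 2 and 3, where 3046 row numbers are skipped, 82.3 times the median gap of 37 between other neighbouring autosomes. A larger gap of 5207 lies between chromosomes 9 and X, where such autosomes would not fall, so a gap of this size is not specific to them. Whether mouse reads were aligned to another species' genome or the values come from RNA of another species is also open, because no other genome was used here.

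Whether the lower RPKM in the cold-storage library reflects a difference between the RPKM divisors of the 2 libraries could not be decided. The 5% quantile of RPKM times span differed by -3.83 on the log2 scale. The 95% bootstrap interval was -4.28 to -3.51 over rows, which are not independent replicates. The median log2 ratio was -3.81 without a pseudocount and -3.50 over the compared rows, the latter just outside that interval. Rows at 0 were 0.863 times as frequent in cold storage as in sham, although a 0 can also be a failed estimate. In simulated libraries with fewer reads at an equal divisor, the low end moved by -0.86 and 0s were 45.4 times as frequent. With only the divisor changed, the low end moved by -3.55, with 193 rows at 0 in each library. Neither run resembled the data, which had 1048 rows at 0 in sham, against 26 in the first run. Both runs drew whole reads at an assumed depth, whereas some values were too small to be whole reads. They therefore cannot decide between fewer reads and a divisor. A divisor moves every row alike in RPKM, so it does not account for all of the spread around the shift: 3 of the most abundant rows had log2 ratios of -0.75, 0.08 and 0.33. On the RPKM + 0.1 scale a divisor moves low rows less. Medians ran from -2.97 at a mean of 0.5 to 1 RPKM to -3.96 at 100 RPKM or more. On that scale 454 of the 962 compared rows lay 2-fold or more from the median, and loci under 1 kb had a median of -2.26. Among the listed rows, a few short ones taking most of the cold-storage reads is argued against by the values. The 3 most abundant rows under 1 kb held at most 1.61% of the reads in the divisor, and 91.1% would be needed. Were that divisor too large by the 14.2-fold difference of the low ends, the bound would be 22.9%, above the limit set for this check. Rows that are not listed could not be checked: row numbers ran to 56038, whereas 3592 rows were listed. An effect of cold storage of the liver on the share of reads at these loci cannot be told apart from a difference between 2 libraries, because there is 1 library per group.

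The 331-bp locus XLOC_039512 on chromosome 6, at 24218 RPKM in cold storage and listed at 0 in the sham library, was the second most abundant row of the table by mean RPKM. An exact 0 can also be a failed estimate, and the locus held at most 0.80% of the reads in the cold-storage divisor.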
